A study of Homo sapiens with 28 samples.

How the data were processed

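RNA was measured in human blood eosinophils obtained by negative selection from healthy volunteers, with each collection divided over 4 conditions. Per the labels' protocols, libraries were made from polyadenylated RNA with a Nextera kit and sequenced as single-end reads of 50 bases on an Illumina HiSeq2500. Reads were mapped to hg38 with TopHat 1.4.1 and counted with HTSeq, whose version is not given in the sources used here, per the submitters' processing notes. The deposited count table holds whole-number counts per gene, not normalized, with 63925 gene rows and 1 column per library. The deposited TPM table holds the same genes as TPM, in which each library sums to 1e+06, per the authors' scaling for gene length and depth. The gene length behind the TPM is not given in the sources used here, and TPM ranks within a library correlated with count ranks at 0.86 to 0.89. The design text names a RefSeq annotation, whereas the row names follow the Ensembl style, and 35424 of them are in GENCODE version 44. That annotation was used for gene positions and transcript lengths. A further 5787 names carry a number marking a repeat of a name, and such genes, close paralogs (TPSAB1 and TPSB2, HBA1 and HBA2, the HLA genes, CCL23) and overlapping genes can divide or share reads, so their values are uncertain. All 33 pseudoautosomal rows have 0 reads in every library. The 470 rows for Y-linked and X-inactivation genes were removed from every table, because the donors are human.

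The main test used edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept with filterByExpr over the 4 groups, which left 12602, library sizes were the totals of all rows, and TMM factors were applied. A quasi-likelihood model with donor and condition was fitted to all 28 libraries, leaving 18 residual degrees of freedom, and each pair of conditions was tested as a contrast with quasi-likelihood F-tests. Calls are at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Standard errors are on the log2 scale, and CPM levels use the same library sizes and TMM factors. The design, the alternatives, the 40 gene lists and the rule for named genes were fixed before the data were examined. For each comparison the rule took up to 12 genes with the largest rise and up to 12 with the largest fall among genes called, moving the same way in all 7 donors and with a mean of at least 5 CPM in the higher group. It also took up to 4 members of each list and a fixed set of receptor, granule and activation genes; the text uses part of these. Lists with at least 3 tested members were tested with limma 3.58.1 camera on voom values, with a preset correlation of 0.01 and again with the correlation estimated per list, with Benjamini-Hochberg adjustment over the lists. Counts of changed members are given at the adjustment over all genes and adjusted over the list alone. Fry was run beside camera. Where a gene had 0 reads in a group, the fold is a lower bound against 3 reads over that group, and with 1 to 3 reads it is the ratio of scaled reads with an exact 95% interval for counting error.

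The donor numbers in the labels pair the libraries, since each collection was divided over the conditions. The deviations of libraries from their group means correlated at a mean of 0.33 (range -0.19 to 0.68) between libraries of 1 donor and -0.08 between donors, and 27 of 28 libraries correlated best with their own donor. No pair of libraries within a group looked like 1 library deposited 2 times, as the lowest chi-square per gene over 84 pairs was 13.8. The libraries came from 2 sequencing runs, with 5 and 2 whole donors, so the donor term also takes up the run, and counts within each run are given beside the pooled ones. Overlaps and correlations between comparisons with shared libraries are given beside simulated unchanged groups and beside disjoint donors. The alternatives were the fit without the donor block, DESeq2 size factors, DESeq2 1.42.0, no filter or a stricter filter, fits of only the groups compared, limma on log2 TPM with pseudocounts of 1 and 0.1, a 2-fold threshold, each run alone, and each donor left out in turn. Library totals without TMM, the smaller run alone and a fit without the 3 libraries that stood apart were added after the data were seen. Other splits of the samples were drawn with a fixed seed, 32 per comparison with the real one.

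The tests were tried on counts simulated from the fitted means of unstimulated cells and the real library sizes. In each comparison 100 genes changed 2-fold and 100 changed 4-fold, as many up as down. The changed genes had an expected mean count of at least 20. Far more genes changed in the real data, so these rates need not hold there. For IL-3 against unstimulated cells, edgeR on 11946 genes recovered 71% of the 2-fold and 98% of the 4-fold changes, with 7 false calls among 176. DESeq2 on 12602 genes recovered 78% and 99%, with 25 false calls among 202. Limma on log2(CPM + 1) recovered 69% and 97%, with 9 false calls among 175, and limma on log2 TPM was not tried on simulated counts. For IL-5 against unstimulated cells edgeR recovered 68% and 95%, with 7 false calls among 170. Camera called a simulated changed list of 20 genes and called 0 of 200 random lists. Simulated genes varied independently, so this does not show how often camera calls unchanged lists of correlated genes. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.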

Results

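Gene expression was measured by RNA sequencing in eosinophils, the granulocytes of allergic and antiparasitic responses, isolated from the blood of 7 healthy donors. The cells of each donor were divided over 4 conditions: unstimulated, or exposed to 10 ng/ml of IL-3, IL-5 or GM-CSF for 48 hours. Each of these cytokines binds its own receptor alpha chain, which pairs with a shared beta chain encoded by CSF2RB. The design asks how the 3 responses compare with the unstimulated state and with each other, and in particular how the response to IL-3 differs from the other 2. There were 7 libraries per condition and 28 in all. The total count per library lay between 5.24e+06 and 1.2e+07 in the unstimulated group, 5.24e+06 and 6.72e+06 with IL-3, 5.06e+06 and 8.15e+06 with IL-5, and 4.55e+06 and 7.46e+06 with GM-CSF. Donors are named A to G. Unless another error is given, values after ± are standard errors of edgeR log2 fold changes from 7 donors per condition.

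The conditions were ordered along the main axis of variation, with unstimulated cells at one end and IL-3 at the other. The first principal component held 37.6% of the variance of log2 CPM, and its mean was -89.4 ± 2.4 (SD, n = 7) in unstimulated cells, 1.2 ± 14.1 with IL-5, 30.2 ± 10.6 with GM-CSF and 58 ± 4.8 with IL-3. The FTL transcript, which encodes ferritin light chain, took 0.776% ± 0.0728 (SD, n = 7) of all reads in unstimulated cells and 3.43% ± 0.935 with IL-3, 2.41% ± 0.644 with IL-5 and 3.51% ± 0.951 with GM-CSF. A single library in each stimulated condition stood apart from the other 6. The median correlation with its own group was 0.884 for IL-3 donor C, where the others lay between 0.943 and 0.953. It was 0.924 for IL-5 donor F, against 0.937 to 0.945, and 0.905 for GM-CSF donor C, against 0.931 to 0.947.

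**Figure D1:**
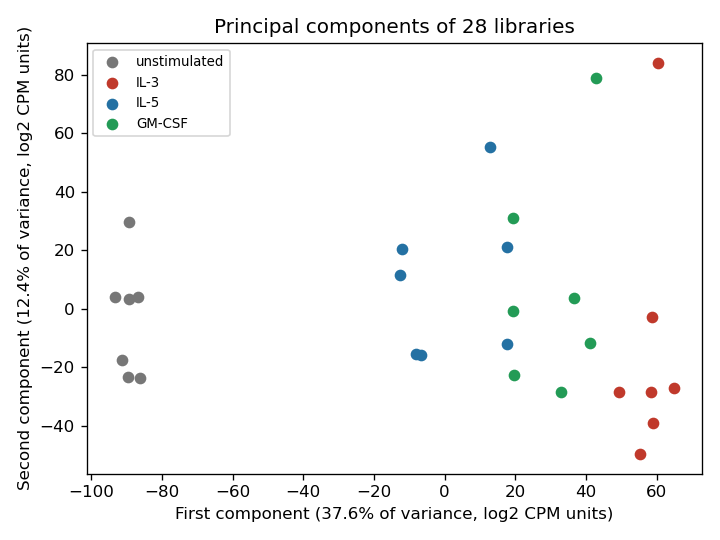
First and second principal components of log2 CPM for the 28 libraries, in log2 CPM units, with the percent of variance on each axis. Each point is 1 library and its colour gives the condition. Along the first component the unstimulated libraries lay between -93.4 and -86.2 and the IL-3 libraries between 49.2 and 64.9, with IL-5 and GM-CSF libraries between them.

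With all 3 cytokines the shared beta chain was higher than in unstimulated cells, and the alpha chain of the IL-5 receptor was lower. The labels do not give the time in culture of the unstimulated cells. Cytokine and time in culture are therefore not separated in these comparisons. CSF2RB (chromosome 22, 36913628 to 36940439, hg38) rose from 707 ± 127 CPM (SD, n = 7) in unstimulated cells to 8970 ± 3180 with IL-3, 2520 ± 859 with IL-5 and 3620 ± 1070 with GM-CSF, in 7 of 7 donors each time. IL5RA (chromosome 3, 3066324 to 3126613) moved the other way, from 1400 ± 326 CPM (SD, n = 7) to 32.3 ± 34.2 with IL-3, 216 ± 110 with IL-5 and 98.9 ± 56.2 with GM-CSF, and was lower in 7 of 7 donors with each. The alpha chains of the IL-3 and GM-CSF receptors, IL3RA and CSF2RA, had 0 reads in every library, as did all 33 gene rows of the pseudoautosomal regions, so their expression cannot be read from these counts. CISH, a STAT5-induced feedback inhibitor of cytokine signalling, rose by 4.09 ± 0.34 log2 units with IL-3, 2.46 ± 0.32 with IL-5 and 2.91 ± 0.32 with GM-CSF. PIM1, a STAT5-induced survival kinase, rose by 2.08 ± 0.14, 0.99 ± 0.14 and 1.37 ± 0.14. CD69, an early activation antigen, rose from 37.3 CPM to 2420, 146 and 502 CPM. FCGR2B, the inhibitory IgG receptor, rose from 22 CPM to 533, 167 and 233 CPM. The granule ribonuclease RNASE2 dropped from 478 CPM to 4.97, 10.1 and 5.19 CPM, and the eotaxin receptor CCR3 from 3600 CPM to 691, 1710 and 1160 CPM. CISH, PIM1, CD69 and FCGR2B were higher, and RNASE2 and CCR3 lower, in 7 of 7 donors with each cytokine.

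**Figure D2:**
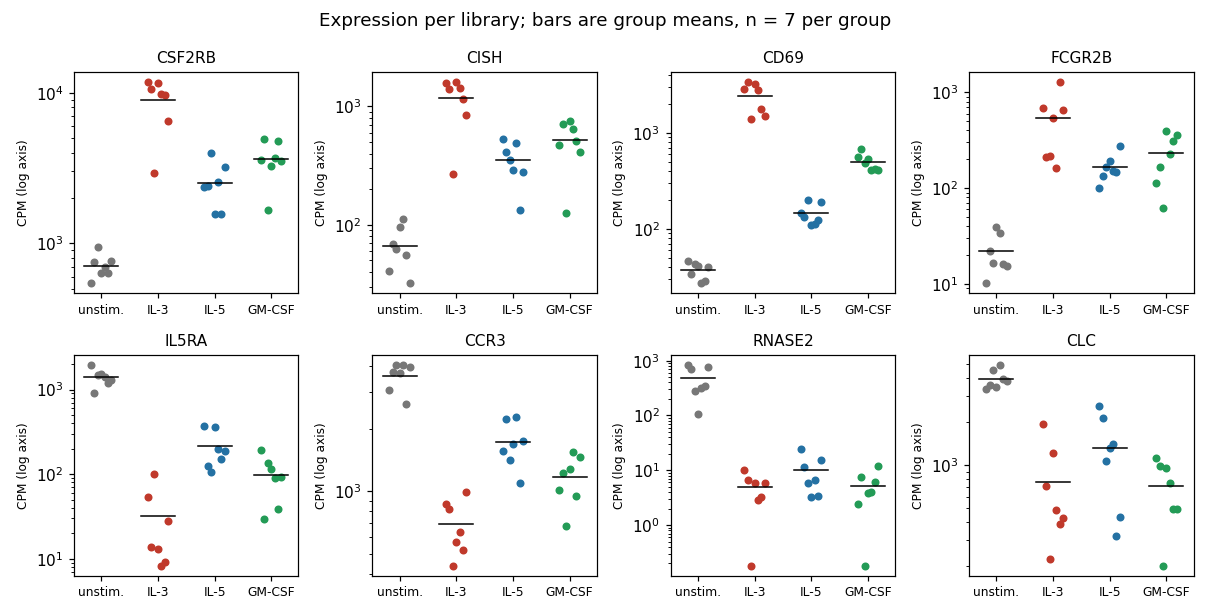
Expression of CSF2RB, CISH, CD69, FCGR2B, IL5RA, CCR3, RNASE2 and CLC in CPM on a log axis. Each point is 1 library, in the same donor order within each condition, and each bar is the mean of the 7 libraries of that condition. The mean of CD69 was 37.3 CPM in unstimulated cells and 2420, 146 and 502 CPM with IL-3, IL-5 and GM-CSF, and the mean of IL5RA was 1400 CPM against 32.3, 216 and 98.9 CPM.

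With IL-3, genes that were nearly silent in unstimulated eosinophils rose, and much of the eosinophil granule and interferon programme fell. CXCL8, a neutrophil attractant, rose by 9.60 ± 0.80 log2 units, CCL2, a monocyte attractant, by 8.72 ± 0.59, and INHBA, the activin A subunit, by 8.56 ± 0.52, each in 7 of 7 donors. CCL24, the ligand eotaxin-2, had 0 reads in unstimulated cells and was at least 313-fold higher. PPARG, a lipid-sensing nuclear receptor (chromosome 3, 12287368 to 12434356), had 3 reads in all unstimulated libraries and was 658-fold higher, with a counting interval of 225 to 3200. RNASE2 fell by 6.56 ± 0.45 and the interferon-induced IFIT2 fell by 7.12 ± 0.37, both in 7 of 7 donors. Floors stand for 3 reads over the group, and floors and intervals cover counting error only.

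Among the genes with the largest rises in all 7 donors were also RASAL1, a Ras GTPase activator (0 reads unstimulated, at least 1180-fold), and CYP1A1, the classic target of the aryl hydrocarbon receptor (2110-fold, interval 723 to 10300). STAC rose by 8.96 ± 0.59 log2 units, PIR by 8.63 ± 0.40 and SEMA6B by 8.59 ± 0.38. Among the largest falls, EHD3 had 0 reads with IL-3 and was at least 125-fold lower, and SCML4 fell by 7.65 ± 0.54. In total 6951 of 12602 genes (55.2%) changed with IL-3, 3504 upward and 3447 downward (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these, 1740 were at least 2-fold higher and 2194 at least 2-fold lower. Within the sequencing run of 5 donors 5606 genes changed, and within the run of 2 donors 4608, and the fold changes of the runs correlated across genes at 0.91. Without the 3 libraries that stood apart 7755 genes changed. With library totals in place of TMM factors, 38.5% of the changed genes were higher, against 50.4%, and limma on log2 TPM gave 2236 higher and 5682 lower.

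Most STAT5 target and feedback genes rose with IL-3, and theirs was the only 1 of 38 lists to pass camera with an estimated correlation. Of 15 tested STAT5 target and feedback genes 13 rose and 1 fell, and the counts were the same adjusted over the list alone. SOCS1 and SOCS2, feedback inhibitors of JAK signalling, rose by 8.23 ± 0.30 and 5.75 ± 0.26, PIM3 by 6.88 ± 0.33 and the cell cycle inhibitor CDKN1A by 5.96 ± 0.18. This list's camera test held with both correlations (Benjamini-Hochberg adjusted p = 1.26e-09, and adjusted p = 0.022 with an estimated correlation). All 13 tested chemokine ligands rose, also adjusted over the list alone (camera adjusted p = 2.06e-07, and adjusted p = 0.0543 with an estimated correlation). Of 24 NF-kB target genes 17 rose and 2 fell, with 17 and 3 adjusted over the list alone, led by CXCL8 and IL1B, the cytokine interleukin 1 beta, at 6.86 ± 0.41 (camera adjusted p = 3.57e-07, and adjusted p = 0.167 with an estimated correlation). Of 24 ERK feedback and immediate early genes 15 rose and 4 fell, with 15 and 5 adjusted over the list alone, including the transcription factors EGR2 at 8.40 ± 0.59 and FOSL1 at 7.06 ± 0.48 (camera adjusted p = 0.00772, and adjusted p = 0.254 with an estimated correlation). Of 12 anti-apoptotic genes 8 rose and 1 fell, with the same counts adjusted over the list alone, led by BIRC3 at 5.31 ± 0.26 and BCL2 at 4.96 ± 0.45 (camera adjusted p = 0.00199, and adjusted p = 0.0543 with an estimated correlation). Of 10 heat shock genes 9 rose, also adjusted over the list alone, with HSPB1 at 3.72 ± 0.39 (camera adjusted p = 8.74e-06, and adjusted p = 0.0543 with an estimated correlation).

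Interferon-stimulated genes fell with IL-3 in 26 of 30 cases and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 6.78e-11, and adjusted p = 0.0543 with an estimated correlation). IFIT2 fell by 7.12 ± 0.37 and XAF1 fell by 6.45 ± 0.64. All 4 tested granule protein genes fell, also adjusted over the list alone (camera adjusted p = 0.00199, and adjusted p = 0.0819 with an estimated correlation). Besides RNASE2 these were the peroxidase EPX, lower by a log2 change of -5.09 ± 0.80, RNASE3 at -3.68 ± 0.34 and CLC, the Charcot-Leyden crystal galectin, at -2.76 ± 0.35. Of 14 eosinophil identity markers 10 fell and 3 rose, with the same counts adjusted over the list alone, the falls including IL5RA, ALOX15 at -2.64 ± 0.30 and SIGLEC8 at -1.73 ± 0.29 (camera adjusted p = 0.00136, and adjusted p = 0.134 with an estimated correlation). The integrin subunit ITGA4 fell by 4.32 ± 0.21, while ICAM1 rose by 3.90 ± 0.31. Of 10 MHC class II and antigen presentation genes 7 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0333, and adjusted p = 0.299 with an estimated correlation).

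Markers of monocytes, platelets, red cells and neutrophils also fell with IL-3, while those of T cells and basophils went both ways. Red cell markers had median log2 changes of -2.96 with IL-3, -2.28 with IL-5 and -2.66 with GM-CSF. For neutrophil markers the medians were -1.19 with IL-5 and -1.41 with GM-CSF. Of 10 monocyte and macrophage markers 7 fell, also adjusted over the list alone, led by VCAN at -7.30 ± 0.36 (camera adjusted p = 0.000937, and adjusted p = 0.0819 with an estimated correlation). Of 7 platelet markers 6 fell and 1 rose, with the same counts adjusted over the list alone, and GP9 fell by 6.82 ± 0.68 (camera adjusted p = 0.00136, and adjusted p = 0.107 with an estimated correlation). Of 14 neutrophil markers 8 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0338, and adjusted p = 0.254 with an estimated correlation). Of 4 T cell markers 1 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.952, and adjusted p = 0.969 with an estimated correlation). Of 10 basophil and mast cell markers 5 rose and 3 fell, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.381, and adjusted p = 0.44 with an estimated correlation). The labels do not say whether the unstimulated cells were also kept for 48 hours in culture, so time in culture and cytokine are not separated in any comparison with them.

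With IL-5, largely overlapping genes differed from unstimulated cells by smaller amounts. CXCL8 rose by 6.88 ± 0.74 log2 units, CCL2 by 6.61 ± 0.56 and SEMA6B by 8.40 ± 0.38, each in 7 of 7 donors, and CCL24 was at least 233-fold higher. The complement component C3 rose by 7.23 ± 0.70 and ENG, the endothelial co-receptor endoglin, by 6.81 ± 0.41. RNASE2 fell by 5.62 ± 0.42, IL5RA by 2.74 ± 0.35, and CPVL, a carboxypeptidase of macrophages, fell by 7.73 ± 0.67, all in 7 of 7 donors. VCAN, a proteoglycan abundant in monocytes, had 1 read with IL-5 and was 2290-fold lower, with a counting interval of 410 to 90300.

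A total of 4215 of 12602 genes (33.4%) changed with IL-5, 2083 upward and 2132 downward (edgeR, Benjamini-Hochberg), with 942 at least 2-fold higher and 1123 at least 2-fold lower. Within runs 3073 genes changed in the 5 donors and 1783 in the 2 donors, with fold changes correlated across genes at 0.83, and 4942 changed without the 3 libraries that stood apart. With library totals 56% of the changed genes were higher, against 49.4%, and limma on log2 TPM gave 2088 higher and 2533 lower. STAT5 target and feedback genes rose in 11 of 15 cases and 1 fell, with the same counts adjusted over the list alone, SOCS1 by 5.39 ± 0.28 and PIM3 by 4.03 ± 0.31 (camera adjusted p = 2.52e-06, and adjusted p = 0.0342 with an estimated correlation). NF-kB target genes rose in 18 of 24 cases and 2 fell, with the same counts adjusted over the list alone, BIRC3 by 5.56 ± 0.26 and IL1B by 5.97 ± 0.40 (camera adjusted p = 1e-11, and adjusted p = 0.0553 with an estimated correlation). Of 13 chemokine ligands 10 rose, with 10 up and 1 down adjusted over the list alone (camera adjusted p = 2.38e-06, and adjusted p = 0.0553 with an estimated correlation). Interferon-stimulated genes fell in 27 of 30 cases and 1 rose, with 27 and 2 adjusted over the list alone, IFIT2 by 3.76 ± 0.30 and MX2 by 3.22 ± 0.30 (camera adjusted p = 3.89e-12, and adjusted p = 0.0342 with an estimated correlation). Tissue remodelling genes rose in 12 of 20 cases and fell in 3, with the same counts adjusted over the list alone (camera adjusted p = 0.00211, and adjusted p = 0.0342 with an estimated correlation). MMP7, a matrix protease, was at least 72.5-fold higher, while TGFBI fell by 5.13 ± 0.65. Cholesterol biosynthesis genes rose in 11 of 24 cases and 1 fell, with 11 and 2 adjusted over the list alone, SQLE by 3.02 ± 0.36 (camera adjusted p = 0.00326, and adjusted p = 0.137 with an estimated correlation). Of 7 cholesterol efflux and LXR target genes 5 fell, also adjusted over the list alone, and ABCA1 fell by 3.32 ± 0.43 (camera adjusted p = 0.00904, and adjusted p = 0.103 with an estimated correlation).

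Of the granule protein genes 3 of 4 fell with IL-5, and 4 adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.0553 with an estimated correlation). EPX did not pass, at -1.36 ± 0.58 (edgeR, Benjamini-Hochberg adjusted p = 0.0729; higher in 2 of 7 donors), but passed with DESeq2 and when donor E or G was left out. SIGLEC8 fell by 0.79 ± 0.28 in 7 of 7 donors (edgeR, Benjamini-Hochberg adjusted p = 0.0307), a call lost without donor B, D, F or G. Markers of monocytes and macrophages fell in 7 of 10 cases, also adjusted over the list alone (camera adjusted p = 2.38e-06, and adjusted p = 0.0342 with an estimated correlation). Platelet markers fell in 6 of 7 cases, and in 7 adjusted over the list alone (camera adjusted p = 3.88e-07, and adjusted p = 0.0277 with an estimated correlation).

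GM-CSF gave changes mostly between those of IL-5 and IL-3 in size. CXCL8 rose by 8.61 ± 0.77 log2 units, CCL2 by 8.22 ± 0.58, PIR by 8.12 ± 0.40 and the interleukin gene IL1A by 7.67 ± 1.20, each in 7 of 7 donors. CCL24 was at least 420-fold higher, and IL6 at least 70.8-fold. RNASE2 fell by 6.45 ± 0.44, IL5RA by 4.05 ± 0.38 and VCAN by 7.80 ± 0.37, all in 7 of 7 donors. SCML4 fell by 7.60 ± 0.53 and MEIS2 fell by 6.52 ± 0.71.

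A total of 5619 of 12602 genes (44.6%) changed with GM-CSF, 2789 upward and 2830 downward (edgeR, Benjamini-Hochberg), with 1287 at least 2-fold higher and 1620 at least 2-fold lower. Within runs 4375 genes changed in the 5 donors and 3048 in the 2 donors, with fold changes correlated across genes at 0.87, and 6333 changed without the 3 libraries that stood apart. With library totals 46.7% of the changed genes were higher, against 49.6%, and limma on log2 TPM gave 2114 higher and 4030 lower. STAT5 target and feedback genes rose in 11 of 15 cases and fell in 2, with the same counts adjusted over the list alone, SOCS1 by 6.29 ± 0.28 and SOCS2 by 3.13 ± 0.23 (camera adjusted p = 1.74e-06, and adjusted p = 0.0394 with an estimated correlation). All 13 chemokine ligands rose, also adjusted over the list alone, CCL22, a type 2 chemokine, by 6.56 ± 0.53 (camera adjusted p = 2.35e-08, and adjusted p = 0.0394 with an estimated correlation). NF-kB target genes rose in 18 of 24 cases and fell in 2, with 18 and 3 adjusted over the list alone (camera adjusted p = 2.18e-10, and adjusted p = 0.0767 with an estimated correlation). Interferon-stimulated genes fell in 27 of 30 cases and rose in 2, with the same counts adjusted over the list alone, and IFIT1 fell by 6.01 ± 0.63 and MX1 fell by 5.69 ± 0.59 (camera adjusted p = 1.09e-12, and adjusted p = 0.0394 with an estimated correlation). Tissue remodelling genes rose in 13 of 20 cases and fell in 3, with the same counts adjusted over the list alone, PLAU, the urokinase gene, by 3.82 ± 0.49 (camera adjusted p = 0.00226, and adjusted p = 0.0394 with an estimated correlation). Heat shock genes rose in 7 of 10 cases, also adjusted over the list alone, HSP90AB1 by 1.72 ± 0.16 (camera adjusted p = 0.00241, and adjusted p = 0.135 with an estimated correlation). All 4 granule protein genes fell, also adjusted over the list alone (camera adjusted p = 0.00241, and adjusted p = 0.0812 with an estimated correlation). The EPX fall of 1.49 ± 0.58 was the least firm (edgeR, Benjamini-Hochberg adjusted p = 0.0398; higher in 2 of 7 donors) and was lost without donor A, B, C, D or F. Markers of monocytes and macrophages fell in 8 of 10 cases, also adjusted over the list alone (camera adjusted p = 5.94e-05, and adjusted p = 0.0515 with an estimated correlation). Platelet markers fell in 6 of 7 cases, also adjusted over the list alone (camera adjusted p = 4.73e-05, and adjusted p = 0.0515 with an estimated correlation).

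The 3 responses shared much of their content. The labels do not give the time in culture of the unstimulated cells, so an effect of that time would also appear as shared by all 3. The 3 cytokines raised 1687 genes and lowered 1743 in common, 3430 in all, and the IL-3 change was larger than the IL-5 change for 2681 of these, with the GM-CSF change between them for 1987. IL-3 and IL-5 shared 1740 raised and 1785 lowered genes, where independent lists of these lengths would share 579 and 583. IL-3 and GM-CSF shared 2451 and 2473 against 775 and 774, and IL-5 and GM-CSF 1889 and 1955 against 461 and 479. Unchanged groups simulated against the shared unstimulated libraries shared at most 0 genes in 4 simulations. No gene truly changed in the simulations, so few calls could arise. They do not measure what the shared libraries add to the overlaps. With disjoint donors for the comparisons, over 6 divisions of the donors into 3 and 4, the median number shared was 1602 for IL-3 and IL-5 (range 801 to 2327; 360 for independent lists), 2108 for IL-3 and GM-CSF (973 to 2329; 478) and 1720 for IL-5 and GM-CSF (1355 to 2365; 333). Fold changes correlated across genes, which are not independent replicates, at 0.82 for IL-3 and IL-5, 0.92 for IL-3 and GM-CSF and 0.94 for IL-5 and GM-CSF, where 20 simulations of unchanged groups gave 0.49. The covariances were 1.01, 1.35 and 0.963, against a simulated 0.038. With disjoint donors the median correlations were 0.75 (range 0.69 to 0.78), 0.83 (0.77 to 0.87) and 0.85 (0.79 to 0.89), and the covariances 0.979, 1.29 and 0.922.

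IL-3 and IL-5 differed in the size of many responses. INHBA was higher with IL-3 by 6.06 ± 0.44 log2 units, the AP-1 factor FOSL1 by 5.97 ± 0.44, SLAMF1, a costimulatory receptor, by 5.95 ± 0.50, PPARG by 7.42 ± 0.65 and CD180, a toll-like receptor homolog, by 6.24 ± 0.46, each in 7 of 7 donors. BCL2, which blocks apoptosis (chromosome 18, 63123346 to 63320128), was higher by 5.42 ± 0.47 and CD69 by 4.03 ± 0.22. ALDH1A2, which makes retinoic acid, had 3 reads with IL-5 and was 306-fold higher with IL-3, with a counting interval of 104 to 1490. CCL23 was higher by 5.66 ± 0.34, although the table counts this gene in more than 1 entry and reads could be divided between them. IL5RA was lower with IL-3 by a log2 difference of -3.05 ± 0.38, IFIT2 by -3.36 ± 0.36 and OXER1, an eicosanoid receptor of eosinophils, by -3.27 ± 0.49, in 7 of 7 donors.

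A total of 4001 genes differed between IL-3 and IL-5, 2036 higher and 1965 lower with IL-3 (edgeR, Benjamini-Hochberg), and 4821 without the 3 libraries that stood apart. Within runs 2180 genes differed in the 5 donors and 2503 in the 2 donors, with a correlation of fold changes of 0.79. With library totals in place of TMM factors 24.3% of the differing genes were higher with IL-3, against 50.9%, and limma on log2 TPM gave 1012 higher and 4043 lower. STAT5 target and feedback genes were higher with IL-3 in 14 of 15 cases, with 14 higher and 1 lower adjusted over the list alone, SOCS2 by 4.34 ± 0.24, IL2RA, the IL-2 receptor alpha chain, by 3.62 ± 0.50 and SOCS3 by 3.37 ± 0.27 (camera adjusted p = 7.14e-14, and adjusted p = 0.00282 with an estimated correlation). ERK feedback and immediate early genes were higher in 16 of 24 cases and lower in 1, with 19 and 2 adjusted over the list alone, DUSP6, a phosphatase of ERK, by 4.03 ± 0.37 (camera adjusted p = 8.94e-08, and adjusted p = 0.0492 with an estimated correlation). Heat shock genes were higher in 9 of 10 cases, also adjusted over the list alone, HSPE1 by 1.97 ± 0.24 (camera adjusted p = 2.45e-09, and adjusted p = 0.0142 with an estimated correlation). MHC class II and antigen presentation genes were higher in 7 of 10 cases, also adjusted over the list alone, and CD80, a costimulatory ligand, by 5.81 ± 1.06 (camera adjusted p = 0.000207, and adjusted p = 0.111 with an estimated correlation). Transcription factors of granulocytes and eosinophils were higher in 10 of 22 cases and lower in 2, with the same counts adjusted over the list alone, IRF4 by 3.39 ± 0.52 and XBP1 by 2.24 ± 0.16 (camera adjusted p = 0.00447, and adjusted p = 0.135 with an estimated correlation). Interferon-stimulated genes were lower with IL-3 in 22 of 30 cases and higher in 1, with 23 and 2 adjusted over the list alone (camera adjusted p = 2.07e-06, and adjusted p = 0.154 with an estimated correlation). Eosinophil identity markers were lower in 9 of 14 cases and higher in 1, with the same counts adjusted over the list alone, ALOX15, a 15-lipoxygenase, by a log2 difference of -2.13 ± 0.30 (camera adjusted p = 0.00119, and adjusted p = 0.154 with an estimated correlation). Basophil and mast cell markers did not move as a group, with 2 of 10 higher and 2 lower, and 2 and 3 adjusted over the list alone. CSF2RB was higher by 1.82 ± 0.28 in 6 of 7 donors.

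IL-3 and GM-CSF differed in fewer genes than IL-3 and IL-5. SLAMF1 was higher by 5.40 ± 0.49 log2 units, CD200, an inhibitory surface glycoprotein, by 5.18 ± 0.69, TNFSF11, the RANK ligand, by 4.51 ± 0.65, BCL2 by 3.96 ± 0.43 and IL2RA by 3.94 ± 0.51, each in 7 of 7 donors. CEACAM1, a homophilic adhesion molecule, was higher by 4.06 ± 0.45 and the plasma glutathione peroxidase GPX3 by 4.10 ± 0.33. The endoglin gene ENG was lower with IL-3 by a log2 difference of -2.34 ± 0.31, PLD4, a nuclease of the phospholipase D family, by -2.23 ± 0.24 and AOAH, which deacylates endotoxin, by -2.08 ± 0.21, all in 7 of 7 donors.

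A total of 1716 genes differed between IL-3 and GM-CSF, 926 higher and 790 lower with IL-3 (edgeR, Benjamini-Hochberg), and 1092 in the fit without the donor block. Within runs 654 genes differed in the 5 donors and 768 in the 2 donors, with a correlation of fold changes of 0.61, and 1119 differed when donor E was left out and 2448 without the 3 libraries that stood apart. With library totals 28.7% of the differing genes were higher with IL-3, against 54%, and limma on log2 TPM gave 536 higher and 1295 lower. STAT5 target and feedback genes were higher in 13 of 15 cases, also adjusted over the list alone, SOCS2 by 2.62 ± 0.22 and SOCS3 by 2.46 ± 0.26 (camera adjusted p = 6.1e-18, and adjusted p = 0.000612 with an estimated correlation). Heat shock genes were higher in 9 of 10 cases, also adjusted over the list alone, HSPE1 by 1.28 ± 0.24 and HSP90AB1 by 0.93 ± 0.16 (camera adjusted p = 1.81e-08, and adjusted p = 0.0214 with an estimated correlation). MHC class II and antigen presentation genes were higher in 8 of 10 cases, also adjusted over the list alone (camera adjusted p = 7.1e-07, and adjusted p = 0.0609 with an estimated correlation). ERK feedback and immediate early genes were higher in 12 of 24 cases and lower in 1, with 13 and 1 adjusted over the list alone, FOSL1 by 3.74 ± 0.37 and PHLDA1 by 2.11 ± 0.34 (camera adjusted p = 3.12e-06, and adjusted p = 0.0627 with an estimated correlation). Eosinophil identity markers were lower in 4 of 14 cases and higher in 1, with 6 and 1 adjusted over the list alone, IL5RA by a log2 difference of -1.74 ± 0.36 and CCR3 by -0.75 ± 0.15 (camera adjusted p = 0.0326, and adjusted p = 0.386 with an estimated correlation). For the granule proteins RNASE2, RNASE3 and CLC no difference passed the test, with log2 differences of -0.12 ± 0.44, -0.39 ± 0.34 and -0.02 ± 0.33 (edgeR, Benjamini-Hochberg adjusted p = 0.918, 0.529 and 0.986; higher with IL-3 in 3 of 7 donors for each). EPX was lower with IL-3 by a log2 difference of -3.59 ± 0.81 in 7 of 7 donors (edgeR, Benjamini-Hochberg adjusted p = 0.00329), at means of 0.198 CPM against 3.4 CPM with GM-CSF, a call lost in the run of 5 donors and with unfiltered TPM.

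IL-5 and GM-CSF gave the most similar profiles. PPARG was lower with IL-5 by a log2 difference of -4.66 ± 0.67, INHBA by -3.50 ± 0.41, CD180 by -3.33 ± 0.41, OSGIN1, an oxidative stress response gene, by -2.20 ± 0.30 and CD69 by -1.76 ± 0.20, each in 7 of 7 donors. CLEC7A, the receptor of fungal beta-glucans also known as dectin-1, was lower by -2.63 ± 0.49 and EGR2 by -2.18 ± 0.39. The interferon-stimulated IFI6 and IFIT2 were higher with IL-5 by 2.80 ± 0.45 and 1.81 ± 0.31, in 7 of 7 donors.

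A total of 315 genes differed between IL-5 and GM-CSF, 111 higher and 204 lower with IL-5 (edgeR, Benjamini-Hochberg), 95 in the fit without the donor block, and 387 without the 3 libraries that stood apart. Within runs 51 genes differed in the 5 donors and 25 in the 2 donors, with a correlation of fold changes of 0.46. With library totals 64.1% of the differing genes were higher with IL-5, against 35.2%, and limma on log2 TPM gave 336 higher and 107 lower. Leaving out donor A, B, D, E, F or G gave 159, 107, 166, 180, 172 and 201 genes, and leaving out donor C gave 658. STAT5 target and feedback genes were lower with IL-5 in 5 of 15 cases, with 8 lower and 1 higher adjusted over the list alone, SOCS2 by a log2 difference of -1.73 ± 0.22 (camera adjusted p = 1.42e-08, and adjusted p = 0.0162 with an estimated correlation). Interferon-stimulated genes were higher in 9 of 30 cases, and 18 adjusted over the list alone (camera adjusted p = 1.37e-11, and adjusted p = 0.0343 with an estimated correlation). Chemokine ligands were lower in 4 of 13 cases, and 9 adjusted over the list alone (camera adjusted p = 6.39e-11, and adjusted p = 0.0162 with an estimated correlation). Heat shock genes were lower in 5 of 10 cases, and 8 adjusted over the list alone, HSPH1 by -0.88 ± 0.17, although the HSPH1 call was lost without donor B (camera adjusted p = 4.98e-09, and adjusted p = 0.0162 with an estimated correlation). ERK feedback and immediate early genes were lower in 4 of 24 cases, and 8 adjusted over the list alone (camera adjusted p = 1.42e-08, and adjusted p = 0.0193 with an estimated correlation). IL5RA was higher with IL-5 by 1.31 ± 0.34 and CCR3 by 0.56 ± 0.15 (edgeR, Benjamini-Hochberg adjusted p = 0.0399 for both; higher in 6 and 7 of 7 donors), and both calls were lost when any donor but C was left out.

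The direct comparisons gave 1604 genes whose expression with IL-3 differed in the same direction from both IL-5 and GM-CSF, 872 higher and 732 lower with IL-3. The balance depended on scaling, with 547 higher and 1408 lower with library totals, and 480 and 1240 with limma on log2 TPM. The like counts were 299 for IL-5 and 4 for GM-CSF. A condition that lies between the other 2 for most genes, as GM-CSF did on the first principal component, can have few such genes. The IL-5 count also cannot exceed the 315 genes that differed between IL-5 and GM-CSF. These counts therefore do not rank the cytokines by how distinct their responses were. Of the 872 genes, 745 were also raised by IL-3 over unstimulated cells, and 254 of these had no call against unstimulated cells with either IL-5 or GM-CSF, while 286 were raised by both. Of the 732 genes, 610 were also lowered by IL-3, 213 of them with no call for the other cytokines and 261 lowered by both. These comparisons share the IL-3 libraries. Independent lists of the same lengths would share 150 higher and 123 lower genes. Simulated unchanged groups shared at most 0, but no gene truly changed in them, so this does not measure what the shared libraries add. With disjoint donors the median number shared was 334 (range 8 to 973, against 25 for independent lists). Within runs the count was 619 in the 5 donors and 733 in the 2 donors, it was 1052 without the donor block and 1045 without donor E. Without the 3 libraries that stood apart it was 2293, of which 1533 were among the 1604.

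Some genes moved in opposite directions. IL-3 and IL-5 gave opposite calls against unstimulated cells for 60 genes, and IL-3 and GM-CSF for 28 (edgeR, Benjamini-Hochberg). IL-5 and GM-CSF gave 0 opposite calls, with 5 at an unadjusted p below 0.05 in edgeR and 1 with DESeq2. Each of the 60 and 28 genes also differed in the direct comparison. Opposite changes from the same libraries add up there, so this was nearly fixed in advance and is no further support. The genes named next were chosen after their values were seen. IL4R, the IL-4 receptor alpha chain (chromosome 16, 27313668 to 27364778), rose by 1.03 ± 0.10 log2 units with IL-3 and fell by 0.37 ± 0.10 with IL-5 and 0.43 ± 0.10 with GM-CSF, in 7 of 7 donors each time. TOX, a transcription factor of lymphoid development, rose by 3.56 ± 0.25 with IL-3 and fell by 1.33 ± 0.26 with IL-5, in 7 of 7 donors both times. DUSP6 rose by 2.15 ± 0.34 with IL-3 and fell by 1.88 ± 0.34 with IL-5, in 7 of 7 donors both times. The aminopeptidase gene ANPEP went the other way, with -0.29 ± 0.11 for IL-3, 1.33 ± 0.11 for IL-5 and 0.97 ± 0.11 for GM-CSF. CEACAM1 rose by 1.74 ± 0.41 with IL-3, in 6 of 7 donors, and fell by 3.37 ± 0.45 with IL-5 and fell by 2.32 ± 0.43 with GM-CSF.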

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

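The tests of explanations in this part were chosen after the results were seen, apart from the counts over other splits of the samples. For the libraries that stood apart, a test on depth was replaced, before it was run, by a test on transcript length once the deviations of single libraries had been viewed. The label test was first computed on group means, without and then with the 3 libraries (0 and 1 of 3 nearest to another group, and 3 of 28 libraries in all), and then replaced by a test on the range of each group. The scaling test was first computed over both directions, then for each, and last for the whole pattern. The share of eosinophils was first tested on T and NK cell markers alone (one-sided permutation tests, p = 0.018, 0.00222 and 0.0119) and then on 3 wider sets of other cell types (highest permutation p = 0.0255), all set against the lists that had fallen most, and these tests were replaced by a test that picks no list. For basophil RNA the bound that would exclude it was changed after its first value was seen.

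Among 72 group values examined for a single distant library, 5 stood out. Chance gives about 1 in 20, so several of the 5 may be due to chance alone. The median correlation with the own group was far below the rest for IL-3 donor C (0.884), IL-5 donor F (0.924) and GM-CSF donor C (0.905). SEMA7A, a semaphorin of activated eosinophils, was at 6.9 CPM in GM-CSF donor C, where the other 6 libraries lay between 14.1 and 19 CPM. EPX was at 0.629 CPM in IL-3 donor G, where the others lay between 0 and 0.217 CPM, near the limit of detection. Responses also differed between cytokines in direction: 60 genes had opposite calls against unstimulated cells with IL-3 and IL-5, and 28 with IL-3 and GM-CSF. Each of these also differed in the direct test, an outcome that opposite calls nearly fix in advance.

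Markers of monocytes, platelets and red cells were higher in unstimulated cells. Their median log2 changes over 20 markers were -2.98 with IL-3, -2.39 with IL-5 and -2.65 with GM-CSF. For 881 genes matched on mean expression the medians were -0.21, -0.03 and -0.13. These argue against a depth effect particular to genes of that expression. They cannot address depth across all genes, because TMM already sets the median of all genes near 0 (0.011, 0.029 and 0.013). Fewer eosinophils with all other cells raised alike cannot be told apart from a loss of single cell types, since 8 marker lists gave permutation p = 0.164, 0.0215 and 0.3, and 0.386, 0.0559 and 0.42 for markers of at least 5 CPM, with IL-3 medians of -1.18, -1.15 and -1.6 for B cell, dendritic cell and neutrophil markers but 0.51 for NK cell markers. The basophil and mast cell list, with a median of 0.65, was left out of these because the cytokine-treated libraries hold much KIT (means of 74.5, 279 and 192 CPM over 7 libraries), and with it p was 0.0079, 0.0002 and 0.0067. RNA of monocytes and platelets that was present in unstimulated libraries and lost in the cytokine cultures may account for part of it, but this was not decided. Of 27 abundant mRNAs of these cells 22 (81.5%) were lower in all 3 comparisons. PPBP went from 144 CPM to 18.9, 16 and 25.4 CPM and PF4 from 33.6 to 4.3, 2.96 and 5.4 CPM. A change of these genes within eosinophils would give the same falls. Against lost RNA stand S100A8, S100A9 and MYL9, which rose with at least 1 cytokine, while 8 of the 27 mRNAs had at least 10 CPM in all 4 groups. The eosinophils were obtained by negative selection, but how completely it removed such cells was not measured here. A change of these genes within eosinophils, by cytokine or by time in culture, was not tested and stays open.

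The 3 libraries that stood apart could not be traced to transcript length, as 0 of 3 had a rank correlation of length and deviation above those of the 18 other cytokine libraries (0.1, 0.16 and 0.07, against -0.17 to 0.22, for 86.5% of genes). RNA of basophils cannot be told apart from a change within eosinophils. All 7 markers other than the mast cell genes KIT, TPSAB1 and TPSB2 lay above the mean of the other libraries in each of the 3. KIT was at 17, 247 and 18.5 CPM against 84, 285 and 220 CPM. The lowest number of the 10 basophil and mast cell markers that were highest in such a library was 2. How completely the negative selection removed basophils was not measured here. The markers HDC and MS4A2 were highest in all 3, HDC at 290, 231 and 550 CPM against means of 34.5, 62.9 and 46.3 CPM in the other libraries. FCER1A was highest in none of the 3, at 58.4, 64.4 and 67.7 CPM against maxima of 76, 102 and 137 CPM in the other libraries. Of the 10 markers, 4, 2 and 5 were highest in IL-3 donor C, IL-5 donor F and GM-CSF donor C. The label of another group is argued against as the whole cause, since 0 of 3 lay within the range of another group, with best median correlations of 0.884 to 0.924 where the lowest of the regular libraries were 0.934 to 0.943. No biological explanation was tested.

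For the 1604 genes with an IL-3 response distinct from both other cytokines, a single shared response that is merely stronger with IL-3 cannot be excluded. Against it, 21 genes were called in opposite directions with IL-3 and another cytokine, each in all 7 donors. These calls are against unstimulated cells, whose time in culture is not given. An effect of that time could turn the sign of a weaker response, so the 21 genes do not decide the question. The 3 libraries that stood apart are argued against, as 95.6% of the genes kept their call without them. Scaling is argued against as the cause of the whole pattern, since 1 factor moves all genes one way and at least 547 genes were called in each direction with TMM, DESeq2 size factors and library totals. For part of the higher and of the lower genes scaling cannot be told apart from a difference in the cells, because total RNA per cell was not measured: with library totals 62.7% of the higher genes kept their call, and the 100% kept among the lower genes decides nothing, since library totals move all genes lower with IL-3 (79.7% over both directions). A difference in signalling between the receptors is named by the design and stays open, as untested.

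For the counts of changed genes only the real split, 1 of 32, gave a count as large in each comparison. With 32 splits no share below 1 of 32 can be seen. The other splits also mix the conditions within both groups, which can raise the residual spread and lower their counts. Chance is therefore not excluded by this test. The real counts were 6951, 4215, 5619, 4001, 1716 and 315 for IL-3, IL-5 and GM-CSF against unstimulated cells, IL-3 against IL-5, IL-3 against GM-CSF and IL-5 against GM-CSF, and the highest of the other splits gave 4314, 2064, 2881, 3939, 71 and 0. The 3939 came from exchanging the labels within 1 donor with a library that stood apart, a split that keeps the real labels of the other 6 donors, and its cause was not tested. For the distinct IL-3 genes 1 of 24 splits, the real one, gave 1604, and the highest other gave 0. Chance is also not excluded for the number of changed gene lists, and in 5 of the 6 comparisons other splits gave as many. As many lists as the real 18, 16, 15, 11 and 9 came from 3, 2, 5, 8 and 3 of 32 splits in the first 5 comparisons, where the highest other splits gave 18, 16, 16, 13 and 9. For IL-5 against GM-CSF only the real split, 1 of 32, gave 14 lists, and the highest other gave 13. Over the other splits the median number of changed lists, at the preset correlation, was 9, 9, 9, 7, 4 and 4 in the 6 comparisons. The median number of changed genes over these splits was 0 in each, so camera p-values at the preset correlation may be too small.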

How the results depend on the processing

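The smaller run alone, library totals without TMM and the fit without the 3 libraries that stood apart were alternatives chosen after the data were seen. Of 218 counts and correlations under an alternative, 44 moved, counts by over 1.5 times and correlations by more than their spread over left-out donors, and 174 did not. The balance of higher and lower genes is not part of this and turned with library totals in all 3 comparisons between cytokines and for IL-3 (3504 and 3447 to 2651 and 4237) and IL-5 (2083 and 2132 to 2451 and 1923) against unstimulated cells. In IL-5 against GM-CSF it went from 111 and 204 to 246 and 138 with library totals and 336 and 107 with limma on log2 TPM. A 2-fold threshold, which by construction admits fewer genes, gave 3934, 2065, 2907, 1709, 683 and 133 genes for IL-3, IL-5 and GM-CSF against unstimulated cells, IL-3 against IL-5, IL-3 against GM-CSF and IL-5 against GM-CSF, and 629 distinct IL-3 genes. In the same order the 2-donor run, with fewer samples, gave 4608, 1783, 3048, 2503, 768 and 25, and 733 distinct. The 5-donor run, which holds all 3 libraries that stood apart, gave 2180 for IL-3 against IL-5, 654 for IL-3 against GM-CSF, 51 for IL-5 against GM-CSF and 619 distinct. Except for IL-5 against GM-CSF these lie below the counts of the 2-donor run. Fewer samples alone therefore does not account for them, and the cause was not tested. Without the donor block IL-3 against GM-CSF, IL-5 against GM-CSF and the distinct count gave 1092, 95 and 1052. IL-3 against IL-5 gave 2626 when only these groups were fitted. IL-5 against GM-CSF gave 633 with DESeq2 and 613 without the low-count filter, and the cause was not tested. Leaving out a donor gave 6327 to 7477, 3437 to 4451, 4914 to 6002, 3115 to 5213, 1119 (without E) to 2304, 107 (without B) to 658 (without C) genes, and 1045 (without E) to 2175 distinct. In IL-5 against GM-CSF each donor left out moved the count by over 1.5 times, with 159 without A, 166 without D, 180 without E, 172 without F and 201 without G. Changed lists numbered 18, 16, 15, 11, 9 and 14 of 38, and fewer in each comparison, 1, 5, 4, 3, 2 and 6, with an estimated correlation. Leaving out a donor gave 16 to 20, 14 to 17, 15 to 19, 11 to 13, 7 to 10 and 9 (without F) to 15 lists. Disjoint donors lowered the correlation of fold changes to 0.75, 0.83 and 0.85. This setting has fewer donors per comparison and also no shared unstimulated libraries, and these were not separated. The genes with the highest expression gave 0.97 for IL-5 and GM-CSF.

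Library totals without TMM moved the median log2 change of all genes to -0.183 for IL-3 against unstimulated cells, -0.284 for IL-3 against IL-5, -0.156 for IL-3 against GM-CSF and 0.115 for IL-5 against GM-CSF, and changes in the text are relative to the TMM scale. Direction changed for 6 of 845 values of single genes in the 2-donor run and in no other alternative: NCF1 with IL-3 (-0.02), HBEGF with IL-5 (-0.13), CTSL with IL-5 (-0.12), GZMB in IL-3 against IL-5 (-0.02), FCGR2B in IL-3 against GM-CSF (-0.06) and CSF1 in IL-5 against GM-CSF (0.03). The cause was not tested. Calls for single genes were lost for 126 without the donor block, 145 in the 5-donor run, 169 in the 2-donor run, 25 with library totals, 15 without the 3 libraries and 6 with DESeq2. Depth limits genes with few reads, where folds are bounds at 0 reads and ratios with wide intervals at 1 to 3 reads.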

Other observations

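The gene lists in this part, and their tests, were chosen after the data were seen. Genes of the antioxidant response driven by NRF2 rose with all 3 cytokines, 17 of 22 with IL-3, 12 with IL-5 and 16 with GM-CSF, with 1 lower each time. Adjusted over the list alone the counts were 17, 12 and 17. PIR, an iron-binding nuclear protein, rose by 8.63 ± 0.40, 6.48 ± 0.41 and 8.12 ± 0.40 log2 units, and SLC7A11, the cystine importer for glutathione synthesis, by 6.76 ± 0.35, 3.80 ± 0.33 and 5.43 ± 0.34, each in 7 of 7 donors. The list's camera test gave Benjamini-Hochberg adjusted p = 9.27e-07, 4.77e-05 and 2.43e-07, and adjusted p = 0.128, 0.17 and 0.11 with an estimated correlation. GCLM, a subunit of the glutathione synthesis enzyme, was higher with IL-3 than with IL-5 by 3.04 ± 0.24. In IL-5 against GM-CSF 10 of 22 were lower with IL-5, with 12 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.95e-16, and adjusted p = 0.0178 with an estimated correlation), with OSGIN1 at -2.20 ± 0.30.

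Targets of the aryl hydrocarbon receptor rose in 6 of 7 cases with each cytokine and 1 fell, with the same counts adjusted over the list alone. AHRR, the repressor of this receptor, rose by 7.85 ± 0.40 with IL-3, 6.48 ± 0.40 with IL-5 and 7.26 ± 0.40 with GM-CSF, and CYP1B1 by 3.70 ± 0.33, 3.28 ± 0.33 and 3.67 ± 0.33. Camera gave adjusted p = 0.000592, 0.000221 and 0.000217, and adjusted p = 0.0828, 0.0532 and 0.0636 with an estimated correlation. Amino acid transporters and tRNA synthetases rose in 14, 11 and 11 of 18 cases and 1 fell each time, with the same counts adjusted over the list alone. The glutamine carrier SLC1A5 rose by 5.59 ± 0.36, 3.60 ± 0.34 and 4.81 ± 0.35, and the leucine carrier SLC7A5 by 3.56 ± 0.30, 2.02 ± 0.29 and 3.02 ± 0.30. Camera gave adjusted p = 7.77e-05, 0.00532 and 0.000307, and adjusted p = 0.0655, 0.147 and 0.0766 with an estimated correlation. NQO1, SLC7A11 and SLC7A5 each belong to more than 1 of these lists. Transcripts of the mitochondrial genome did not move as a list, with 2 of 13 higher and 3 lower with IL-3, and the same counts adjusted over the list alone (camera adjusted p = 0.665, and adjusted p = 0.913 with an estimated correlation).

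The response to a cytokine was also compared between the sequencing runs, a test chosen after the data were seen. No gene passed the test, with 0 of 12602 for IL-3, IL-5 and GM-CSF (edgeR, Benjamini-Hochberg). At an unadjusted p below 0.05 in edgeR, the only tool run for this test, there were 432, 413 and 342. The runs hold 5 and 2 donors, and the power of this test was not measured. The 0 calls therefore do not show that the responses were the same in both runs.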
